A study of Escherichia coli with 3 samples.

How the data were processed

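The series holds 3 two-colour spotted arrays of Escherichia coli MG1655, each setting RNA of a cueO mutant (Cy5) against wild-type RNA (Cy3). The deposited values are log2 ratios of the channels for each spot, with neighbouring duplicate spots kept apart, and no centring by the authors is visible in them. How the spots were scanned, filtered or background-corrected is not given in the sources used here, nor is which channel was the numerator. The base of the logarithm was read from the values themselves, since ratios of small whole numbers recur as log2 values. Channel intensities were not used here, so dim spots could not be filtered and no intensity-dependent correction could be made. The arrays are titled cueO 1500V, cueO 2500V and cueO 3500V. Whether these titles number replicates, cultures or slides or name a scanner setting is not given in the sources used here, so what n = 3 counts beyond arrays is open, and replicates are numbered in the order of deposition.

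Of 14400 spots per array, 9012 carried a gene name in the platform annotation and 5388 did not. The annotation held 25 symbols under 2 gene identifiers each. For these only the spots of the identifier that matched the MG1655 gene table were used, which left out 50 spots. Identifiers of 4131 genes matched that table and 17 did not, and no symbol changed. Missing spots numbered 238, 234 and 304 on arrays 1 to 3. Another 22, 17 and 24 values stood at a cap of 16.61 and were treated as missing. Spots of a gene were averaged (2 spots for 4096 genes, 4 for 35, 6 for 5, 26 for 11 and 314 for dnaK), and 4130 genes with a value on all 3 arrays were tested out of 4148 named, leaving 18 out.

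Each array was centred on the median of its genes. These medians were -0.84, -1.20 and -0.95 as deposited, so directions are relative to the median gene and a shift common to all genes cannot be seen. The log2 ratio of mutant over wild type was tested against 0 in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, intercept only, two-sided), with Benjamini-Hochberg adjustment over all genes tested and an adjusted p under 0.05 as the threshold. The prior degrees of freedom came to 6.33. Errors are SDs over the 3 arrays. Gene lists of at least 3 measured members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over 31 lists. They were tested again with an estimated correlation and with fry. With an estimated correlation camera uses the residual degrees of freedom of 3 arrays, so hardly any list could pass. Its adjusted p therefore cannot decide for or against a list. List medians are relative to the median of all genes. The members ybdZ, marA, cpxP and aroG were not measured.

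The comparisons, the 31 lists and the named-gene rule were fixed before the data were examined. The rule named cueO, the 12 highest and 12 lowest genes by mean log2 ratio among those past the threshold with 1 sign on all arrays, up to 4 members of each list with the smallest p, and every measured member of the copper and neighbour lists. Other settings fixed in advance were no centring, scaling, quantile normalization, genes on at least 2 arrays, the median over spots, eBayes with robust=TRUE, a one-sample test per gene with unmoderated variance, treat against a fold of 1.5, all spots in place of genes for correlations, camera with an estimated correlation, fry, and leaving out each array. Scaling used the median absolute value per array, because limma's scale method could not run on centred ratios.

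Several choices were made after the data were seen. These are the treatment of capped values as missing, the centre taken over genes in place of all spots, the handling of symbols under 2 identifiers, and 5 further settings. These settings are centring each print block of 300 spots, centring on all spots, leaving out 58 genes with spots over 1 log2 unit apart, leaving out 112 genes as a stand-in for dim ones, and keeping capped values. The stand-in took genes with at least 50% of their values at ratios of whole numbers up to 20. A further 15 lists were chosen after the top genes were seen, were tested with and without the 12 highest and 12 lowest genes, and are kept to the closing part, apart from 1 median given beside the ribosomal list.

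The per-gene test was tested on simulated data with 200 changed genes and variances drawn from the prior that limma fitted to these arrays. A single draw varied, so it was repeated over 20 draws. The draws hold no print-block effect, dye effect or correlation between genes, and far fewer changed genes than the 1385 called in the data. The share of false calls in them therefore follows from the model and does not measure that among the real calls. On average 21.3% of genes changed 1.5-fold were found (range 11.9 to 29.9%), 86.6% of those changed 2-fold (71.6 to 97.0%) and 98.9% of those changed 3-fold (93.9 to 100%), and 4.78% of the calls were false (at most 8.81%). The set test called a list shifted by 0.5 and 0 of 40 unchanged lists, in simulated genes that are independent of each other, which real genes of an operon are not: neighbouring genes of the chromosome correlated at 0.358 here, and genes 10 apart at 0.0227. SDs between duplicate spots were 0.133, 0.156 and 0.115 on arrays 1 to 3.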

Results

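The series asked what the multicopper oxidase CueO does in Escherichia coli. CueO is a periplasmic enzyme of copper tolerance that can oxidise Cu(I) and Fe(II). Transcript levels of a cueO mutant of strain MG1655 were set against those of its wild-type parent on 3 two-colour DNA microarrays. Both strains were grown in a minimal medium (M9C) with 2 µM iron to an OD600 of 0.8. On every array the mutant RNA carried Cy5 and the wild-type RNA carried Cy3, so a dye effect and a strain effect cannot be told apart. Any difference of stock between the strains other than cueO cannot be told apart from an effect of cueO either. The labels disagree with each other in 2 places. The second channel of array 3 has a mutant strain label but a wild-type source name, and the wild-type iron is given as ferrous in the source name and as ferric chloride in the design text. If the design text is right, iron source and strain differ together and cannot be told apart. The labels speak of triplicate cultures without saying that each array took a culture of its own, so the p-values measure the spread between these arrays, which may be partly technical. The wild type's spread enters the ratios only as far as each array took wild-type RNA of its own, and it cannot be told apart from the mutant's.

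Each array held 14400 spots, most genes being printed as 2 neighbouring spots, and 4130 named genes were measured on all 3 arrays. Values are log2 ratios of mutant over wild type, given as mean ± SD over the arrays (n = 3) after each array was centred on its median gene. Which channel was divided by which is not given in the sources used here. The direction taken, Cy5 over Cy3, is likely because the labels list the mutant as the first channel and cueO itself was low on all 3 arrays. The value of cueO is weak support, since 649 genes passed as lower in that direction. All directions are relative to the median gene: in the ratios as deposited the median of all genes lay 1 log2 unit lower, and a gene with a centred mean under 1 has a deposited mean below 0. The precision is limited by the number of arrays, and with 3 arrays an exact two-sided sign-flip test cannot give a p under 0.25.

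The cueO transcript (locus b0123) was lower in the mutant in the direction taken, which its own values helped to choose. Its log2 ratios were -0.60, -0.90 and -0.65 on arrays 1 to 3, a mean of -0.71 ± 0.16 (n = 3), so that the wild type held 1.64-fold more (limma adjusted p = 0.00816). Which part of the gene the probe covers is not given in the sources used here, and a ratio does not show whether any cueO transcript was present in the mutant. Without array 3 the mean was -0.75 and the adjusted p 0.0535, so the call was lost with a mean no smaller.

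The 12 genes with the largest increases in the mutant included 4 of mixed-acid fermentation. The formate channel gene focA stood highest at 3.24 ± 0.51, which is 9.45-fold. Its operon partner pflB, for pyruvate formate-lyase, rose by 2.32 ± 0.52, the acetate kinase gene ackA by 2.67 ± 0.66, and grcA, for a spare part of pyruvate formate-lyase, by 2.56 ± 0.54 (each n = 3). The autotransporter adhesin gene flu rose 7.79-fold (2.96 ± 0.48), the ferrous iron uptake gene feoA 5.98-fold (2.58 ± 0.34), and hisG, for the first enzyme of histidine synthesis, 5.51-fold (2.46 ± 0.66). The other members of the 12 highest were bidA at 2.49 ± 0.82, ydfZ at 2.45 ± 0.61, the universal stress protein gene uspF at 2.42 ± 0.37, the dihydroxyacetone kinase gene dhaK at 2.41 ± 0.63 and the outer membrane protein gene ompW at 2.41 ± 0.55. Their limma adjusted p ran from 1.52e-04 for flu to 7.27e-04 for bidA, and all 12 were higher on each array.

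The 12 genes with the largest decreases included galactitol, glycerol and flagellar genes. Of the galactitol transport and catabolism operon, gatC fell to -3.15 ± 0.68, gatA to -2.75 ± 0.62 and gatD to -2.48 ± 0.61, so that wild type held 8.88-fold more of gatC. The glycerol genes glpK (glycerol kinase, -2.47 ± 0.45), glpC (a subunit of the anaerobic glycerol 3-phosphate dehydrogenase, -2.41 ± 0.45) and glpF (the glycerol channel, -2.21 ± 0.28) fell too. The flagellin gene fliC fell to -2.63 ± 0.17, which leaves 6.17-fold more in wild type, and the hook gene flgE fell to -2.14 ± 0.42. The other 4 of the 12 lowest were yjbB (-2.19 ± 0.32), sfmC (-3.31 ± 0.92), yahL (-2.30 ± 0.96) and ybeR (-1.95 ± 0.97). The spots of the last 3 differed from each other by 1.90, 1.28 and 0.51 log2 units on average, so their sizes are uncertain. Adjusted p ran from 1.52e-04 for fliC to 0.00286 for ybeR, and all 12 were lower on each array.

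**Figure D1:**
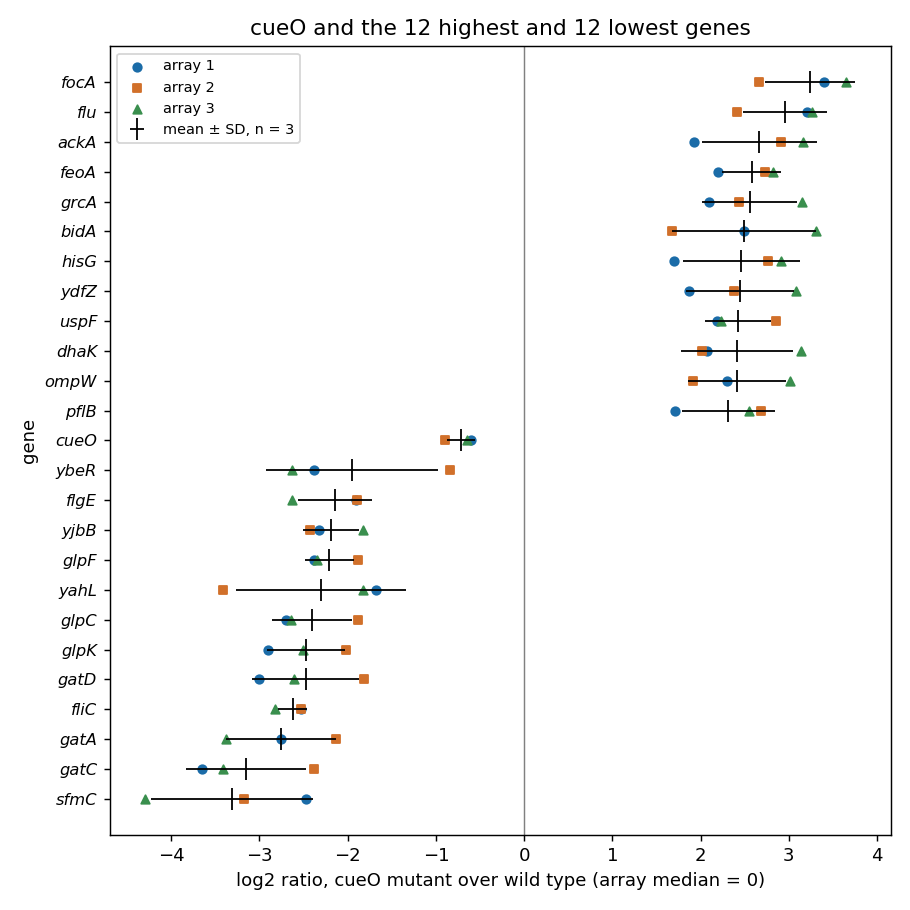
Log2 ratio of cueO mutant over wild type, with each array's median gene at 0 (horizontal axis), for cueO and the 12 highest and 12 lowest genes (vertical axis). Symbols are single arrays and black marks the mean ± SD (n = 3): focA lies at 3.24 ± 0.51, cueO at -0.71 ± 0.16 and gatC at -3.15 ± 0.68, and without centring all values would lie about 1 log2 unit lower.

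Over all 4130 genes, 1385 passed an adjusted p of 0.05 (limma), 736 higher and 649 lower in the mutant, which is 53.1% higher. Of these, 165 were higher and 149 lower by over 2-fold. The sign was the same on all 3 arrays for 2672 genes (64.7%; 25% by chance) and for 1382 of the 1385 that passed. The split depends on the centre: centred on all spots in place of genes, a setting chosen after the data were seen, 999 were higher and 410 lower (70.9% higher), and without centring 51 were higher and 3470 lower (1.45% higher). Were the channels divided the other way round, these shares would be 46.9%, 29.1% and 98.6% higher. Without array 1, 686 genes passed and without array 3, 539, while the moderated test against a fold of 1.5 left 154 and the unmoderated test left 0.

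The copper genes moved both ways around cueO. Of 12 measured members of the copper list, 2 rose and 5 fell (3 and 6 adjusted over the list alone). The genes of the Cus efflux system fell: cusC, for its outer membrane channel, to -1.37 ± 0.21 (adjusted p = 8.00e-04), cusB to -0.87 ± 0.25, cusA, the pump, to -0.52 ± 0.30 and cusS, the sensor kinase, to -0.48 ± 0.16. The copper ATPase gene copA rose by 1.03 ± 0.33 (2.05-fold, adjusted p = 0.00318), as did bhsA, for an outer membrane stress protein, by 0.79 ± 0.38. The remaining members did not pass: cusF was at -0.41 ± 0.036, comR at 0.41 ± 0.12, cueR at 0.32 ± 0.90, cutC at -0.11 ± 0.15 and cusR at -0.10 ± 0.26. As a list they were not set apart from other genes (median -0.25; camera adjusted p = 0.292, and adjusted p = 0.477 with an estimated correlation), though fry, which tests the list on its own, gave an adjusted p of 0.0229. Without array 3 only cusC was still lower past the threshold (adjusted p = 0.0533 for cusB and 0.235 for cusA, with cusS lost as well), and without array 1, 3 fell and bhsA did not pass (adjusted p = 0.0828). Centring on all spots ended the calls of cusS and cusA and turned cutC and cusR to 0.024 and 0.026, without array 3 cueR lay at -0.014 and cusR at 0.018, without array 2 cueR passed at 0.83 (adjusted p = 0.00116), and without centring bhsA, comR and cueR lay below 0 and copA at 0.033.

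Among the 8 genes that neighbour cueO on the chromosome, 3 rose and none fell (the same count adjusted over the list alone). The spermidine synthesis genes speD and speE, which lie near cueO, rose by 1.14 ± 0.27 and 0.98 ± 0.28 (adjusted p = 0.00180 and 0.00323), and hpt, for a purine salvage enzyme, rose by 0.46 ± 0.17 (adjusted p = 0.0440). The genes next to cueO on either side, yacC (0.32 ± 0.55) and gcd (-0.29 ± 0.52), did not pass, nor did can (0.11 ± 0.19), yadG (-0.12 ± 0.96) and yadH (0.030 ± 0.53), and yadG was -1.22 on array 2 but 0.36 and 0.52 on arrays 1 and 3. The list's median was 0.22 (camera adjusted p = 0.172, and 0.459 as the adjusted p with an estimated correlation), and it passed without array 2 (camera adjusted p = 0.0326) and without centring (0.0412). The call of hpt was lost whichever array was left out (adjusted p = 0.145, 0.0794 and 0.129 without arrays 1, 2 and 3), yadG turned positive and passed without array 2 at 0.44 (adjusted p = 0.0407), yacC also passed without array 2 at 0.62 (adjusted p = 0.00822), yadH lay at -0.23 without array 3, and without centring speE, hpt, yacC, can and yadH lay below 0.

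Iron storage genes rose relative to the median gene. Of the 5 measured, 4 passed: bfr, for bacterioferritin, by 1.66 ± 0.22 (3.16-fold, adjusted p = 3.96e-04), dps, for the iron-binding DNA protection protein, by 1.52 ± 0.27, ftnA, for ferritin, by 1.01 ± 0.082 and ftnB by 0.48 ± 0.28 (4 adjusted over the list alone). The list's median was 1.02 (camera adjusted p = 0.0101, but adjusted p = 0.357 with an estimated correlation). The ferrous iron uptake operon rose as well, feoA by 2.58 ± 0.34, feoB by 1.29 ± 0.52 and feoC by 0.95 ± 0.74, while efeB of another ferrous system was at -0.29 ± 0.070 and did not pass. The 7 genes of that list, 3 of which rose (3 adjusted over the list alone), had a median of 0.19 and were not past the set test (camera adjusted p = 0.0812, and 0.443 as the adjusted p with an estimated correlation). That list passed without array 1 (just under the threshold), without centring (camera adjusted p = 8.95e-04) and by fry (adjusted p = 0.0253). The call of ftnB was lost whichever array was left out (adjusted p = 0.117, 0.114 and 0.122) and that of feoC without array 3 (adjusted p = 0.112), and without centring ftnB and feoC lay below 0.

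Ferric iron acquisition did not move as a group. Of 9 enterobactin genes only entS, for the siderophore exporter, passed, and it fell to -0.74 ± 0.72 (adjusted p = 0.0490; 0 adjusted over the list alone). The synthesis genes entA (0.48 ± 0.35), entB (0.36 ± 0.40) and entE (-0.37 ± 0.097) did not pass. Of 23 genes of ferric siderophore and citrate uptake, 4 rose and 1 fell (4 and 0 adjusted over the list alone). Those that rose were exbD (1.04 ± 0.61) and exbB (0.60 ± 0.16), which energise outer membrane transport, fecB (0.69 ± 0.34) and fiu (0.53 ± 0.23). The medians were -0.26 for enterobactin and -0.12 for ferric uptake (camera adjusted p = 0.692 and 0.702, and 0.817 for each as the adjusted p with an estimated correlation). With print blocks centred 2 enterobactin genes rose and 3 fell, and 3 ferric uptake genes fell. Without array 2, 2 enterobactin and 2 ferric uptake genes fell, and without array 3, 0 of each fell and 2 ferric uptake genes rose. Without array 3 the call of entS ended (adjusted p = 0.263), with exbB (0.0755) and fiu (0.0850). Without array 1, 1 ferric uptake gene rose and the calls of exbB (0.0743), fecB (0.129) and fiu (0.111) ended, fiu also missed without array 2 (0.0556), and without centring entA, entB, exbB, fecB and fiu lay below 0.

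Genes for iron-using enzymes that the small RNA RyhB lowers were higher on balance: 5 of 12 rose and none fell (6 adjusted over the list alone). The fumarate reductase genes frdA (1.49 ± 1.12) and frdB (1.10 ± 0.88), the succinate dehydrogenase gene sdhA (0.83 ± 0.52) and the iron superoxide dismutase gene sodB (0.52 ± 0.070) were among them. The median was 0.40 (camera adjusted p = 0.0435, but adjusted p = 0.459 with an estimated correlation), and the set call was also lost without array 2 (adjusted p = 0.123), with print blocks centred (0.0626), centred on all spots (0.0579) and by fry (0.0954). Without array 1, 2 genes rose and without array 3, 3. The calls of sdhA (0.0761) and sodB (0.111) were lost without array 1, and those of frdA (0.0502), frdB (0.0986) and sodB (0.104) without array 3. Such a loss need not mean a smaller change, as sodB was much alike on arrays 1 to 3 (0.46, 0.60 and 0.51). Without centring sdhA and sodB lay below 0.

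Iron-sulfur cluster assembly genes showed little change. Of 6 Suf genes, 1 passed, sufA at 0.46 ± 0.094 (adjusted p = 0.0390), and of 8 Isc genes 1 passed, the regulator gene iscR, which fell to -0.84 ± 0.27 (adjusted p = 0.00592). Adjusted over the list alone, 0 Suf genes rose and 1 Isc gene fell. The others named by the rule were sufD (0.35 ± 0.28), sufC (0.29 ± 0.15), sufS (-0.32 ± 0.30), iscX (0.41 ± 0.31), fdx (0.28 ± 0.17) and iscA (-0.29 ± 0.30), none of which passed. List medians were 0.26 and -0.15 (camera adjusted p = 0.431 and 0.552, and 0.817 for each as the adjusted p with an estimated correlation). The call of sufA was lost without array 1 (0.211) or 3 (0.163) and that of iscR without array 3 (0.0589), and without array 2, 3 Suf genes rose and 2 Isc genes fell, sufD (0.0185) and iscA (0.0313) among them. With print blocks centred 3 Suf and 2 Isc genes rose. Without centring all of these with a positive mean lay below 0.

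Of 14 measured genes of the SoxRS superoxide response, 9 rose and 1 fell (9 and 1 adjusted over the list alone). The manganese superoxide dismutase gene sodA rose by 1.15 ± 0.44 (2.22-fold), the ferredoxin reductase gene fpr by 0.99 ± 0.30, the flavodoxin gene fldA by 0.76 ± 0.13 and the endonuclease gene nfo by 0.91 ± 0.42. The regulator gene soxS itself, named after its value was seen, was at 0.044 ± 0.31 and did not pass (adjusted p = 0.859). The list's median was 0.49 (camera adjusted p = 0.0216, but adjusted p = 0.357 with an estimated correlation and 0.0737 without centring, where fpr, fldA and nfo lay below 0). Without array 1, 3 genes rose and without array 3, 2, with nfo lost in each (adjusted p = 0.0563 and 0.0728) and fldA without array 3 (0.0535).

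Other stress lists gave mixed results. Of 10 genes of the OxyR peroxide response, 2 rose, fur (0.54 ± 0.22), for the iron regulator Fur, and katG (0.47 ± 0.22), for catalase, but 0 adjusted over the list alone, and trxC (-0.33 ± 0.16) and yaaA (-0.37 ± 0.52) did not pass. Of 8 Cpx envelope stress genes, 3 rose (the same count adjusted over the list alone): yccA by 1.34 ± 0.18, the response regulator gene cpxR by 0.87 ± 0.20 and the sensor gene cpxA by 0.47 ± 0.065, while ppiA was at 0.49 ± 0.42. Of 12 zinc and nickel genes, 4 rose, among them the zinc regulator gene zur (2.01-fold) and the zinc uptake genes znuA (0.85 ± 0.12) and znuC (0.83 ± 0.18), and 1 fell, nikE of nickel uptake (-0.80 ± 0.17; the same counts adjusted over the list alone). Of 15 heat shock genes, 2 rose and 3 fell (2 and 5 adjusted over the list alone). The chaperone genes dnaK (-0.80 ± 0.091, over 314 spots) and htpG (-0.85 ± 0.20) fell, and rpoH (0.75 ± 0.099), for the heat shock sigma factor, and the protease gene clpP (0.77 ± 0.28) rose. The 314 spots of dnaK spanned 2.20 log2 units per array on average, a range over far more spots than other genes have. They add no further arrays. The medians were 0.080, 0.39, 0.075 and -0.29 in that order, and no list passed the set test (camera adjusted p = 0.752, 0.0812, 0.290 and 0.216, and 0.817, 0.616, 0.477 and 0.619 as adjusted p with an estimated correlation), though the zinc and nickel list passed by fry (adjusted p = 0.0229). Calls lost without array 1 were those of fur (0.0962), katG (0.0979), cpxA (0.142) and nikE (0.0509). Without array 3 those of fur (0.0925), katG (0.168), cpxA (0.137), rpoH (0.0567) and clpP (0.0724) were lost and 0 heat shock genes rose, 7 heat shock genes fell with print blocks centred, katG also missed without array 2 (0.0794), where trxC (0.0477) and yaaA (0.00545) passed as lower, the Cpx list passed without array 3 (camera adjusted p = 0.0338), where the OxyR median lay at -0.041, and without centring every named gene of these lists with a positive mean except yccA and zur lay below 0.

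Acid resistance and general stress genes rose together. Of 10 genes of glutamate-dependent acid resistance, 8 rose and none fell (8 adjusted over the list alone). The glutamate decarboxylase genes gadB and gadA rose by 2.19 ± 0.099 and 2.08 ± 0.19, the antiporter gene gadC by 1.84 ± 0.27 and the acid chaperone gene hdeA by 1.93 ± 0.22. The near-identical sequences of gadA and gadB can cross-hybridise, so their separate values are uncertain. Of 16 genes under the general stress sigma factor RpoS, 11 rose and none fell (13 adjusted over the list alone), among them wrbA (2.19 ± 0.39), elaB (1.79 ± 0.14), the transketolase gene tktB (1.67 ± 0.41) and the pyruvate oxidase gene poxB (1.64 ± 0.36). The rpoS transcript itself, named after its value was seen, was at -0.18 ± 0.17 and did not pass. The medians were 1.17 and 0.88 (camera adjusted p = 1.73e-06 and 1.35e-05, but adjusted p = 0.357 for each with an estimated correlation).

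Flagellar and chemotaxis genes were the 1 list that passed as lower. Of 48 genes 39 fell and 1 rose (the same counts adjusted over the list alone). The decrease reached 6.17-fold for flagellin (fliC) and 3.57-fold for the filament cap gene fliD (-1.84 ± 0.12), and the export gene fliR fell to -1.93 ± 0.065. The spots of fliR differed by 0.58 log2 units on average, so its size is uncertain. Of the genes for the master regulator FlhDC, flhD fell to -0.51 ± 0.11 and flhC was at -0.11 ± 0.25 and did not pass. The single gene that rose was flgJ, at 0.49 ± 0.23, and flhD, flhC and flgJ were picked after their values were seen. The list's median was -0.93 (camera adjusted p = 1.15e-14, but adjusted p = 0.357 with an estimated correlation). Without array 3, 22 genes fell and without array 1, 27, and flgJ did not pass whichever array was left out. For comparison, the spots with no gene name, centred alike, had a median of -0.27.

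**Figure D2:**
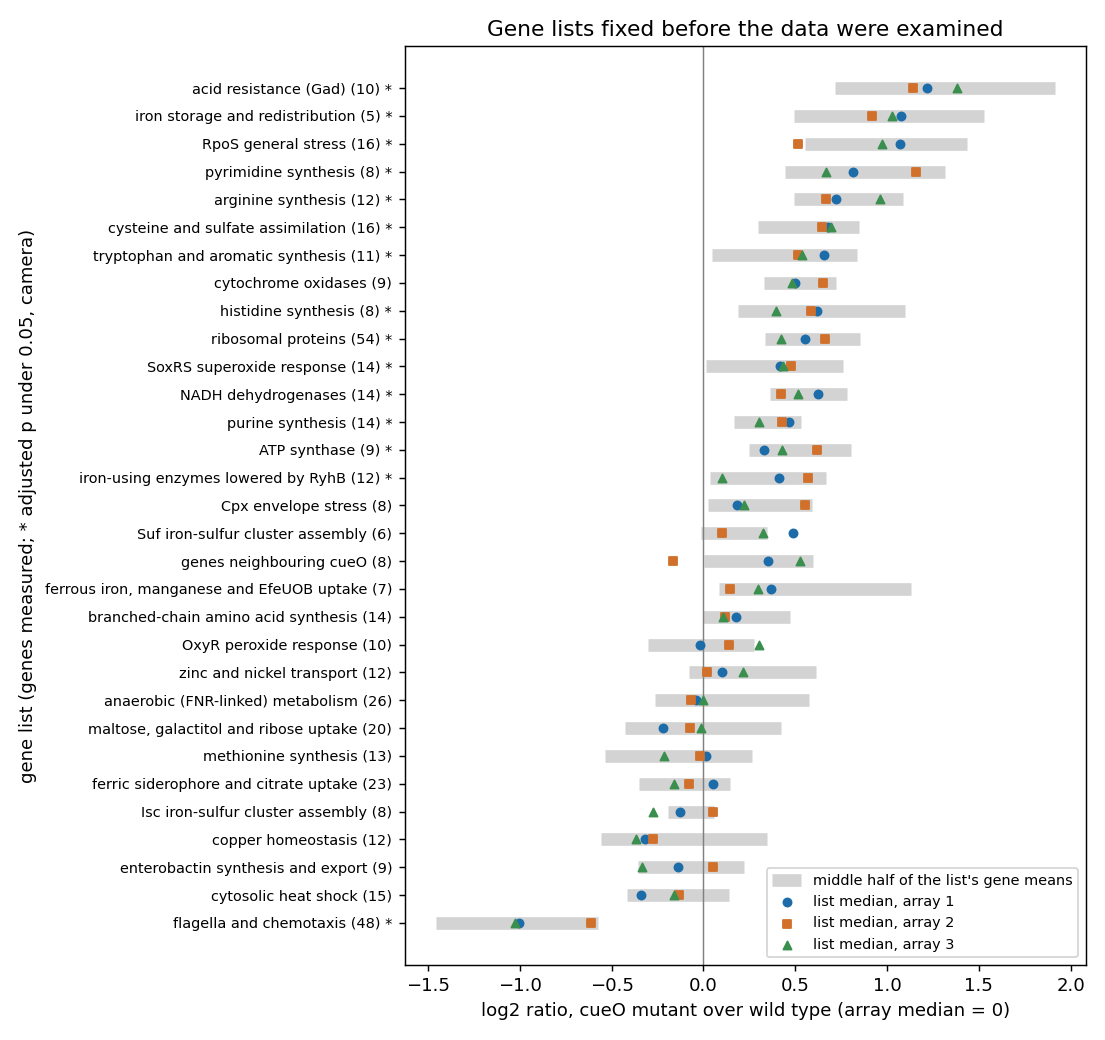
Gene lists fixed before the data were examined (vertical axis, with the number of genes measured and a star for a camera adjusted p under 0.05) against log2 ratio of cueO mutant over wild type, each array's median gene at 0 (horizontal axis). Symbols are list medians on single arrays and grey bars the interquartile range of gene means: the Gad list lies highest (median 1.17) and flagella lowest (-0.93), and without centring all values would lie about 1 log2 unit lower.

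Ribosomal protein genes rose in large number relative to the median gene. Of 54 measured, 32 rose and none fell (37 adjusted over the list alone), among them rplC (1.17 ± 0.28), rpsJ (1.15 ± 0.28), rplR (1.10 ± 0.31) and rpmJ (1.01 ± 0.21). Their median was 0.54 (camera adjusted p = 4.69e-10, but adjusted p = 0.357 with an estimated correlation). Without array 1, 19 rose and without array 3, 19. Other abundant transcripts, a list chosen after the data were seen, had a median of 0.62, and without centring all 4 named genes lay between 0.011 and 0.17. A ratio that rises with signal strength was not ruled out for this list or for any other list called as higher or lower.

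Respiratory chain genes were higher on balance too. Of 14 NADH dehydrogenase genes, 5 rose and none fell (9 adjusted over the list alone), with nuoA at 1.28 ± 0.24, nuoC at 0.98 ± 0.15, nuoM at 0.87 ± 0.037 and nuoB at 0.85 ± 0.30. Of 9 ATP synthase genes, 4 rose (5 adjusted over the list alone), with atpB at 1.06 ± 0.018, atpH at 0.86 ± 0.26, atpA at 0.79 ± 0.21 and atpE at 0.48 ± 0.12. Medians were 0.48 and 0.41 (camera adjusted p = 2.65e-04 and 0.00709, but adjusted p = 0.357 for each with an estimated correlation, and 0.180 for ATP synthase without centring). Of 9 cytochrome oxidase genes, 5 rose (6 rose and 1 fell adjusted over the list alone), among them cyoB (0.94 ± 0.28), cyoE (0.71 ± 0.20), cyoC (0.67 ± 0.32) and cyoA (0.62 ± 0.32) of the bo oxidase. That list's median of 0.63 did not pass (camera adjusted p = 0.0542, and 0.357 as the adjusted p with an estimated correlation), though it did without array 2 (camera adjusted p = 0.0277) or array 1 (just under the threshold), with quantile normalization (0.0462), with scaling (just under the threshold) and by fry (0.0241). Without array 2, 10 NADH dehydrogenase genes rose, as did 12 with print blocks centred and 12 centred on all spots, and without array 1 or 3, 2 oxidase genes rose. The calls of cyoC (0.0516 and 0.0649) and atpE (0.125 and 0.123) were lost without array 1 or 3, that of cyoA without array 1 (0.107) and that of cyoE without array 3 (0.0689), and without centring the named genes except nuoA and atpB lay below 0.

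Anaerobic metabolism genes did not rise as a group, although focA, pflB and adhE did. The alcohol dehydrogenase gene adhE rose by 1.76 ± 0.60 (3.39-fold). Of 26 genes of anaerobic metabolism linked to the oxygen sensor FNR, 4 rose and 2 fell (the same counts adjusted over the list alone). Among those that fell, narH of nitrate reductase was at -0.75 ± 0.33. The median was -0.0051 but the mean 0.30, and the set test pointed upward without passing (camera adjusted p = 0.552, and 0.817 as the adjusted p with an estimated correlation), though it passed without centring (camera adjusted p = 0.0279). The call of narH was lost without array 1 (0.0707), and without array 2, 7 genes rose and 5 fell. With print blocks centred 6 fell, and without array 1, 0.

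Amino acid synthesis genes were higher in several pathways. Of 16 genes of sulfate assimilation and cysteine synthesis, 10 rose and none fell (10 adjusted over the list alone), with the sulfate-binding gene sbp at 1.36 ± 0.32, cysJ at 1.18 ± 0.15, cysK at 1.10 ± 0.082 and cysA at 0.80 ± 0.15. Of 12 arginine genes, 6 rose and none fell (10 adjusted over the list alone), with argC at 1.54 ± 0.28, argG at 1.16 ± 0.45, argF at 2.83-fold and argI at 1.05 ± 0.27. The last 2 are related in sequence and may cross-hybridise, which was not examined, so their separate values are uncertain. Of 8 histidine genes, 4 rose and none fell (the same count adjusted over the list alone), led by hisG and hisD (1.65 ± 0.83), with hisC at 0.90 ± 0.42 and hisI at 0.81 ± 0.29. Of 11 genes of tryptophan and aromatic synthesis, 6 rose and none fell (the same count adjusted over the list alone), with trpE at 1.37 ± 0.19, trpA at 1.21 ± 0.29, trpD at 0.95 ± 0.066 and trpB at 0.71 ± 0.022. The medians were 0.75, 0.81, 0.60 and 0.71 in that order (camera adjusted p = 5.88e-04, 9.65e-05, 0.0229 and 0.0191, but adjusted p = 0.357, 0.357, 0.357 and 0.458 with an estimated correlation). Without array 1, 6 cysteine and 3 aromatic genes passed, without array 2, 10 arginine genes, and without array 3, 4 aromatic genes. The call of trpB was lost without array 1 (0.0524) or 3 (0.0524) and that of hisC without array 3 (0.0668), and without centring cysA, hisC, hisI, trpB and trpD lay below 0.

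Methionine and branched-chain synthesis did not follow. Of 13 methionine genes, 1 rose, metE (0.92 ± 0.14), for the cobalamin-independent methionine synthase, and 4 fell, among them metA (-0.80 ± 0.39), metF (-0.76 ± 0.50) and the regulator gene metR (-0.54 ± 0.12; the same counts adjusted over the list alone). Of 14 branched-chain genes, 3 rose, ilvG (1.57 ± 0.69), leuD (0.62 ± 0.065) and ilvM (0.72 ± 0.60), and ilvB was at 0.50 ± 0.41 without passing (2 rose adjusted over the list alone). Medians were -0.10 and 0.10 (camera adjusted p = 0.523 and 0.205, and 0.626 and 0.458 as adjusted p with an estimated correlation). Calls lost without array 3 were those of metA (0.0933), metF (0.137), metR (0.105), leuD (0.0674) and ilvM (0.208), and without array 1 those of metR (0.158), leuD (0.0804) and ilvM (0.0538). Without array 2 ilvB passed (0.0438). Centred on all spots, 2 methionine genes fell and 5 branched-chain genes rose, against 1 without array 1 or 3. Without array 3, 0 methionine genes fell, and without centring metE, leuD, ilvM and ilvB lay below 0.

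Nucleotide synthesis genes rose relative to the median gene. Of 8 pyrimidine genes, 5 rose and none fell (the same count adjusted over the list alone), with the aspartate transcarbamoylase genes pyrB at 1.53 ± 0.46 and pyrI at 1.49 ± 0.68, pyrC at 1.25 ± 0.31 and pyrG at 1.08 ± 0.24. Of 14 purine genes, 7 rose and none fell (9 rose and 1 fell adjusted over the list alone), with purL at 0.89 ± 0.19, purH at 0.82 ± 0.091, purT at 0.57 ± 0.24 and purD at 0.53 ± 0.25. Medians were 0.83 and 0.48 (camera adjusted p = 0.00386 and 0.0145, but adjusted p = 0.409 and 0.357 with an estimated correlation). The purine call was also lost without array 1 (camera adjusted p = 0.0562, 2 genes risen) and without centring (0.246), where the 4 named purine genes lay below 0, and 3 purine genes rose without array 3. The gene purD missed whichever array was left out (0.0754, 0.0570 and 0.131), and purT missed without array 1 (0.141) or 3 (0.0560).

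Sugar uptake genes split within 1 operon. Of 20 genes for maltose, galactitol and ribose, 5 rose and 6 fell (the same counts adjusted over the list alone). Besides gatA, gatC and gatD, which fell, the first gene of the galactitol operon, gatY, rose by 1.59 ± 0.62, while gatZ (0.20 ± 0.51) and gatB (-0.24 ± 0.037), also named after their values were seen, did not pass. The maltose activator gene malT rose by 1.63 ± 0.24 (adjusted p = 4.77e-04). The list's median was -0.035 (camera adjusted p = 0.737, and 0.817 as the adjusted p with an estimated correlation). Without array 1 or 3, or centred on all spots, 3 genes fell, and without array 1 the list's median lay at 0.011.

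In all, 15 of the 31 lists passed camera with a preset correlation of 0.01, 14 as higher and 1 as lower. With an estimated correlation 0 passed, the smallest adjusted p being 0.357. That setting cannot decide, because the few residual degrees of freedom of 3 arrays let hardly any list pass. Even the Gad list, with an estimated correlation of -0.105, gave an adjusted p of 0.357. By fry, which tests each list on its own, 18 passed, 14 of them among the 15.

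The arrays ran the same way. Across genes, which are not independent replicates, the Pearson correlation of log2 ratios was 0.685 between arrays 1 and 2, 0.817 between 1 and 3 and 0.663 between 2 and 3 (Spearman 0.670, 0.797 and 0.633), and the SD over genes was 0.585, 0.695 and 0.662. Neighbouring spots of a gene correlated at 0.949, 0.951 and 0.970. On array 2 the print block of a gene took up 22.5% of the variance of gene values, against 2.80% on array 1 and 6.88% on array 3, and with each block centred the mean correlation between arrays rose from 0.722 to 0.806. Array 3, whose second channel has the doubtful label, correlated no worse with array 1 than array 2 did.

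**Figure D3:**
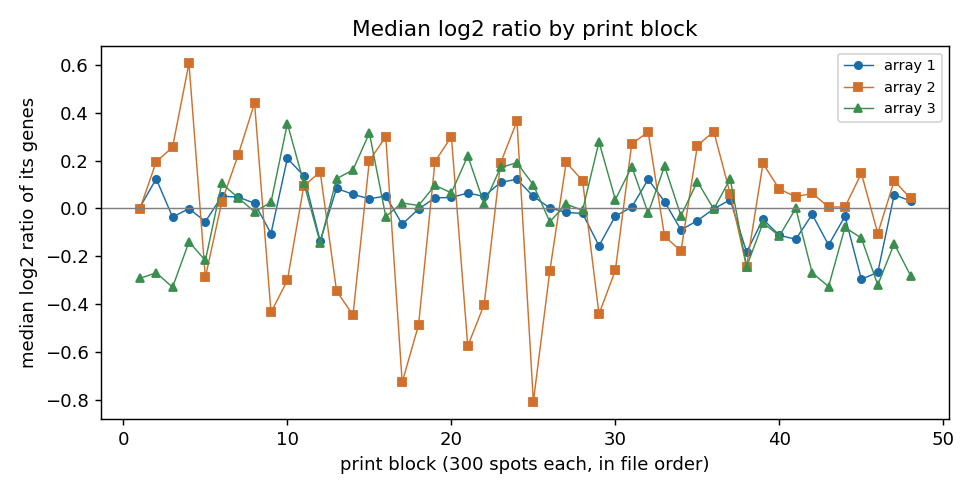
Median log2 ratio of the genes in each print block of 300 spots (vertical axis, array median at 0) against the number of the block in file order (horizontal axis), a line per array. Block medians run from -0.81 to 0.61 on array 2, from -0.29 to 0.21 on array 1 and from -0.33 to 0.35 on array 3.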

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

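Most tests in this part use lists, settings or spots chosen after the data were seen. The exceptions are the turning of an array's sign and, in part, the tests of the array with a mutant label on both channels. For that array the flagellar list and the correlation between arrays were used, which were fixed before the data were examined. The use of the flagellar list for that purpose and the bounds of both tests were set after the data were seen. The bounds for signal strength and print blocks were set before their outcome was computed. The 5388 spots with no gene name enter no comparison. Tested on their own, some of them passed the threshold, which without intensities does not show a signal over background. Of 4954 tested, 32 were higher in the mutant (0.646%, 20 of them over 2-fold) and 432 lower (8.72%), with a median log2 ratio of -0.27. Of 8885 named spots, 1447 were higher (16.3%) and 1549 lower (17.4%). Were the channels divided the other way round, higher and lower would change places. Centred on their own median, 16 unnamed spots were higher and 16 lower. What these spots carry is not given in the sources used here.

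Ribosomal protein genes were higher on balance (median 0.54). Uneven print blocks are excluded as the whole cause, because the median with each block centred was 0.55, and 0.55, 0.70 and 0.43 on arrays 1 to 3. A ratio that rises with signal strength stays open and may account for the pattern. The other abundant transcripts had a median of 0.62 (0.52, 0.85 and 0.54 on arrays 1 to 3), against 0.55, 0.66 and 0.42 for the ribosomal genes. The median of 0.62 met the bound set beforehand for this explanation, a median not far below the ribosomal one. These values still cannot decide, because channel intensities were not used. The list of other abundant transcripts also holds genes of translation, transcription and glycolysis, such as tufA, rpoB and pgk. These may be regulated together with the ribosomal genes. Centring on all spots moved the ribosomal median by 0.12, but a single constant per array moves every gene alike and so cannot decide. A faster or slower growth of the mutant is a biological explanation that was not tested.

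Genes of the glycerol regulator GlpR were lower, 7 of 9 past the threshold with a median of -1.49, and of -1.93, -1.05 and -1.51 on arrays 1 to 3. Without glpK, glpC and glpF, which prompted the list, 4 of 6 fell with a median of -0.81 (camera adjusted p = 0.0186, but adjusted p = 0.428 with an estimated correlation). Spots that failed singly are excluded, since 0 of these genes had spots differing by over 0.5 on average. A fault shared by the neighbouring spots of a gene cannot be excluded this way. Weaker activation by cAMP-CRP could lower them, but the list of other genes it activates had a median of -0.25 (-0.21, -0.12 and -0.23 on arrays 1 to 3), between the bounds set for either answer. A stock difference other than cueO cannot be told apart from an effect of cueO, because the regulon's median of -1.49 comes from 1 mutant strain, which the labels call isogenic.

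Array 3 has a mutant strain label on both channels. Had both channels held mutant RNA, the flagellar genes would lie near 0 there, apart from any dye effect. Their median on array 3 was -1.02 (bootstrap standard error over genes 0.18, which treats genes of an operon as independent). This argues against mutant RNA on both channels only if a dye effect did not lower these genes. The dyes ran the same way on every array, so that cannot be checked. A rescan of another array is excluded, as the highest correlation of array 3 across genes with another array was 0.817. A wrong strain label remains as a possible explanation, and array 3 regressed on the mean of arrays 1 and 2 gave a slope of 0.899 (r = 0.798).

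With 3 arrays there are 4 patterns of signs, too few for a share under 0.05. The real one gave 1385 genes past the threshold, 1 of the 4 gave as many (the real one itself), and the highest of the others gave 0.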

How the results depend on the processing

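The print-block, all-spot, spot-agreement, dim stand-in and capped-value settings were chosen after the data were seen. No paired analysis was possible because there is 1 group and each array is already a ratio. As reported, 1385 genes passed (736 higher and 649 lower), with 3 neighbours, 15 lists and a mean correlation between arrays of 0.722. Scaling, quantile normalization, genes on at least 2 arrays, the median over spots, eBayes with robust=TRUE (which has no form in camera as run for gene lists) and both filters on genes moved none of these counts by over 1.5 times and turned no named gene. Of 150 named-gene results besides cueO, 148 kept direction and side of the threshold under scaling, 149 under quantile normalization and 150 with the median over spots. Precision is limited by the number of arrays, and signal over background cannot be judged without intensities.

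Without centring, all genes shift by 1 log2 unit downward by construction: 3521 genes passed, 51 higher and 3470 lower, 901 of them shared with the 1385. There 57 named genes reversed: bhsA -0.21, comR -0.59, cueR -0.68, entA -0.52, entB -0.64, exbB -0.40, fecB -0.30, fiu -0.47, feoC -0.049, ftnB -0.52, sdhA -0.17, sodB -0.48, sufA -0.54, sufD -0.65, sufC -0.71, iscX -0.59, fdx -0.72, fpr -0.011, fldA -0.24, nfo -0.087, fur -0.46, katG -0.53, cpxR -0.13, cpxA -0.53, ppiA -0.51, znuA -0.15, znuC -0.17, rpoH -0.25, clpP -0.23, cyoB -0.056, cyoE -0.29, cyoC -0.33, cyoA -0.38, nuoC -0.020, nuoM -0.13, nuoB -0.15, atpH -0.14, atpA -0.21, atpE -0.52, cysA -0.20, metE -0.077, leuD -0.38, ilvM -0.28, ilvB -0.50, hisI -0.19, hisC -0.098, trpD -0.054, trpB -0.29, purL -0.11, purH -0.18, purT -0.43, purD -0.47, speE -0.017, hpt -0.54, yacC -0.68, can -0.89 and yadH -0.97. The unmoderated test per gene left 0 genes changed, 0 higher and 0 lower, and 0 neighbours (at an unadjusted p under 0.05, 1183 genes against 1885 by limma), with cueO at -0.71 but an adjusted p of 0.138. Treat against a fold of 1.5 left 154 genes, 88 higher and 66 lower, and 0 neighbours, with cueO at -0.71 and an adjusted p of 1. Over all alternatives the adjusted p of cueO ran from 0.00105 to 1. Camera with an estimated correlation left 0 lists.

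Centred on all spots, 410 genes were lower and 999 higher, all genes shifting by 0.13, and cutC (0.024), cusR (0.026) and yadG (0.012) reversed. With each print block centred 1926 genes passed, 979 higher and 947 lower, and 1334 of them were shared with the 1385. The mean correlation rose to 0.806 in that setting and yadG reversed (0.081). Keeping capped values lowered the correlation to 0.620. By quantile normalization the anaerobic list's median reversed to 3.97e-04. The cause of these reversals was not tested beyond the shift itself.

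Leaving out 1 array at a time gave 539 to 1638 genes changed, 312 to 861 higher and 227 to 777 lower, the lowest without array 3 and the highest without array 2, and 666 of the genes without array 1, 1273 without array 2 and 534 without array 3 were shared with the 1385. The cueO ratio ran from -0.77 to -0.62. Reversing within their ranges were yadG (-0.43 to 0.44), cueR (-0.014 to 0.83), cusR (-0.24 to 0.018), yadH (-0.23 to 0.30), the maltose, galactitol and ribose list (-0.063 to 0.011) and the OxyR list (-0.041 to 0.15), and the cause was not tested. Without arrays 1, 2 and 3, 26, 5 and 33 named genes besides cueO fell short of the threshold, and without array 2, 8 others passed it, yadG among them with its sign turned.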

Other observations

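The 15 lists in this part were chosen after the results were seen, and several hold genes already named. Its single genes were chosen after too, apart from gatA, gatC, gatD and uspF, which the rule fixed in advance had named. Of 10 fermentation genes 8 rose (median 1.47), and without the 4 among the 12 highest genes 4 of 6 did (median 0.78; camera adjusted p = 0.0366, but adjusted p = 0.428 with an estimated correlation). Of 14 glycolysis genes 12 rose (median 1.03; camera adjusted p = 3.41e-07, but adjusted p = 0.323 with an estimated correlation). Adjusted over the list alone, 9 fermentation genes rose and 1 fell, and the glycolysis count was the same. Fatty acid synthesis genes (7 of 12 rose, median 0.52, camera adjusted p = 0.00583) and abundant transcripts (17 of 27 rose, median 0.62, camera adjusted p = 3.41e-07) were higher too, but with adjusted p = 0.369 and 0.323 with an estimated correlation. Universal stress genes (4 of 7 rose, median 0.67) did not pass without uspF, which was seen first (camera adjusted p = 0.105, and adjusted p = 0.428 with an estimated correlation). Colanic acid genes (6 of 16 fell, median -0.45, camera adjusted p = 0.00583) and cAMP-CRP activated genes (9 of 35 fell and 2 rose, median -0.25, camera adjusted p = 0.0399) were lower, but with adjusted p = 0.323 for each with an estimated correlation. Spots with no gene name, centred alike, had a median of -0.27, so the cAMP-CRP activated genes lay no lower than those. None of the 15 lists passed with an estimated correlation (smallest adjusted p = 0.323), and 11 passed by fry, among them the 8 that passed camera with all members kept.

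The other lists did not pass camera. All 5 opp genes of the peptide permeases fell (list median -0.60, adjusted p = 0.0637) while dppA rose by 0.98 ± 0.29. Medians were -0.24 for phosphate starvation (adjusted p = 0.0637), -0.47 for curli (0.0875), 0.26 for the TCA cycle (0.115) and -0.22 for fatty acid degradation (0.382). Type 1 fimbriae had a median of -0.16 but a mean of 0.038 (adjusted p = 0.964), and for nitrogen starvation the median was 0.016 and the mean 0.0043 while the set test pointed downward (adjusted p = 0.948).

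Single genes with a bearing on several lists were crl, for a partner of RpoS, which rose by 1.36 ± 0.25 (adjusted p = 8.83e-04), and flhD, which fell to -0.51 ± 0.11 (adjusted p = 0.0280). The GlpR regulator gene glpR rose by 0.68 ± 0.10 (adjusted p = 0.00898). The galactitol operon ran from 1.59 for gatY through 0.20 for gatZ, -2.75 for gatA, -0.24 for gatB and -3.15 for gatC to -2.48 for gatD, with its regulator gene gatR at 0.0099. Stocks of MG1655 are known to differ in glpR, gatC, crl and upstream of flhDC. A difference of stock may therefore lie behind part of the lower GlpR regulon (median -1.49). The same holds for the galactitol genes, the flagellar list (median -0.93) and the RpoS list (median 0.88). For none of these can it be told apart from an effect of cueO, and a second, independent cueO mutant would be needed to test this.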
